A study of Homo sapiens with 20 samples.

How the data were processed

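Messenger RNA was measured in 20 libraries, each a sort-purified population from human blood or tonsil, placed in 7 groups by the cell type the labels give. Per the labels' protocols, RNA was isolated on magnetic beads and amplified with the SMART-seq Ultra low input kit, which copies full-length transcripts and does not mark the strand. Per the submitters' processing notes, the tools were bcl2fastq, HISAT2 2.0.2 and HTSeq, and the genome build was hg19 (GRCh37). The options, the annotation and the treatment of strand are not given in the sources used here. The deposited values are raw whole-number counts of reads per gene symbol, one table per library, with no normalization. No coordinates are printed because the files give symbols only.

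Each table held 25369 genes and 5 summary entries of the counting program (reads in no gene, ambiguous reads, low quality, not aligned, not uniquely aligned). These summary entries name no gene and stayed out of library sizes and tests. Reads assigned to genes made up 62.67% to 69.16% of all entries in the blood and tonsil ILC3 libraries and 35.77% to 62.79% in ILC1. The gene total was 19020801 to 40017678 reads per library. Reads of a gene and of an overlapping or antisense gene cannot be told apart without strand. Reads of near-identical copies such as HSPA1A with HSPA1B or XCL1 with XCL2 are split in a way that is uncertain. The reads carry no molecular identifiers, so counting intervals and floors cover counting error only. The labels do not say which libraries came from separate donors, so p-values measure only the spread between these libraries.

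Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered with filterByExpr by group, which left 16841 genes, and scaled by TMM. One quasi-likelihood fit (glmQLFit and glmQLFTest) held all 20 libraries with a mean per group, which left 13 residual degrees of freedom, because groups of 2 or 3 libraries give little information on their own spread. The spread was thus shared over both tissues, though tonsil replicates differed more from each other than blood replicates. In fits of only 1 tissue, chosen after seeing the data, every blood comparison called more genes and every tonsil comparison fewer. In each of 7 comparisons p-values were adjusted by Benjamini-Hochberg and called under 0.05. CPM values used the TMM-scaled library sizes. Principal components were taken on log2 CPM with a prior count of 2. Where a group had no read of a gene, the fold is a lower bound against a floor of 3 reads over the group, and with 1 to 3 reads it is a ratio with a 95% counting interval. For lists, the median was also taken with such genes at their bound.

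The comparisons, the tests, 23 gene lists and the rule for named genes were set before the data were examined. The lists, which cover markers of lymphocyte subsets, pathways and other cell types the gates could hold, had 417 entries in the files. They were tested with camera on voom values with a preset correlation of 0.01, again with the correlation estimated per list, and with fry, and adjusted over the lists within a comparison. Calls of members are given over all genes and adjusted over the list alone. The named genes were the 10 per direction in the comparison of the ILC2 subsets, and 6 in the others, with the largest log2 fold change among called genes. They had a mean of at least 10 CPM in the higher group and no overlap between the groups. Added to them were KIT, CCR6, NCR2, NCAM1, PTGDR2 and IL7R in every comparison and up to 4 members of each list with the smallest adjusted p. From these the text gives examples, and some genes that vary strongly between people were left unnamed. Left out of the ranking were 107 genes of X inactivation and the Y chromosome, segments of antigen receptors, and loci without a standard gene name. The tonsil gene sets came from a separate fit of the 9 tonsil libraries, as the 100 genes per direction with the smallest p at a log2 fold change over 1.

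Replicates of a group were compared before averaging. Of 19 pairs, 0 held identical counts, and the chi-square per degree of freedom of their counts, over genes with at least 20 reads, ranged from 44.29 to 413.6, so no library was a repeat of another in its group. The range was 44.29 to 82.42 within blood groups and 86.19 to 413.6 within tonsil groups. The number in the source name was checked as a pairing, by the correlation of deviations from the group means. Between Kit+ CCR6+ and Kit- ILC2 it was 0.133, 0.146 and 0.134 for the same-numbered libraries, all over 0.1, so the fit with the number as a block is given beside that comparison for the count and for the sort and marker genes that did not pass without it.

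Alternatives were size factors by relative log expression, no filter on low counts, the DESeq2 Wald test, a fit of only the groups compared, a fit with the replicate number as a block, and each library left out in turn. For the tonsil gene sets, 50 and 200 genes per direction were also tried. Added after seeing the data were fits of 1 tissue, fits without the ILC1 libraries, and fits without libraries that held transcripts of other cell types. A group left with 1 library was assumed to vary like the other groups. The procedure was tested on simulated data for the ILC2 comparison over 16841 genes. There 14.9% of genes changed 2-fold, 65.7% of those changed 4-fold and 81.8% of those changed 8-fold were called, with 6 false calls. The changed genes were drawn only from those above a minimum mean level in the ILC2 libraries. Every library was simulated with the same spread per gene, so these shares do not cover a spread that differs between blood and tonsil.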

Results

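Gene reads were counted in 20 RNA-seq libraries of innate lymphoid cells and natural killer (NK) cells sorted from human blood and tonsil. Innate lymphoid cells (ILC) are lymphocytes without rearranged antigen receptors. ILC1 are known for interferon gamma, ILC2 for type 2 cytokines and the transcription factor GATA3, and ILC3 for interleukin 17 and 22 and the receptor tyrosine kinase Kit. The 11 blood libraries fell into Kit- ILC2 (n = 3), Kit+ CCR6+ ILC2 (n = 3), ILC3 (n = 2) and CD56high NK cells (n = 3). The 9 tonsil libraries fell into NKp44- ILC3, NKp44+ ILC3 and ILC1 (n = 3 each), where NKp44 is the activating receptor encoded by NCR2. Between 19020801 and 40017678 reads per library were assigned to genes, and 12619 to 16639 genes had at least 1 read. Kit- ILC2 were less deeply read (19020801 to 26091702 reads) than Kit+ CCR6+ ILC2 (27297816 to 35577531 reads). Levels are given in CPM, which are counts scaled to library size, with their SD, and log2 fold changes with an approximate standard error (SE). This SE is the absolute log2 fold change over the square root of the F statistic, so it reflects the spread of the shared fit.

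Component 1 of the variation followed tissue and component 3 cell type in blood, while on component 2 a single library stood far apart. Component 1 held 24.22% of the variance and had every tonsil library at 61.73 or above and every blood library at -33.91 or below. Component 2 held 16.93%, and its lowest values were those of the ILC1 libraries, with ILC1 replicate 2 at -270.3. ILC1 replicates 1 and 3 lay at -91.38 and -50.07, and all other libraries at -17.41 or above. ILC1 replicate 2 also had the lowest share of reads in genes, 35.77%, followed by ILC1 replicate 1 at 45.09%. The summed B and plasma cell markers ranged from 288.8 CPM in ILC1 replicate 3 to 7184 CPM in ILC1 replicate 2. Cell type, library quality and B lineage transcripts thus cannot be told apart on component 2. Component 3 held 12.44%, with CD56high NK libraries at 123.3 to 129.5 and both blood ILC2 groups at -63.74 to -55.51.

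**Figure D1:**
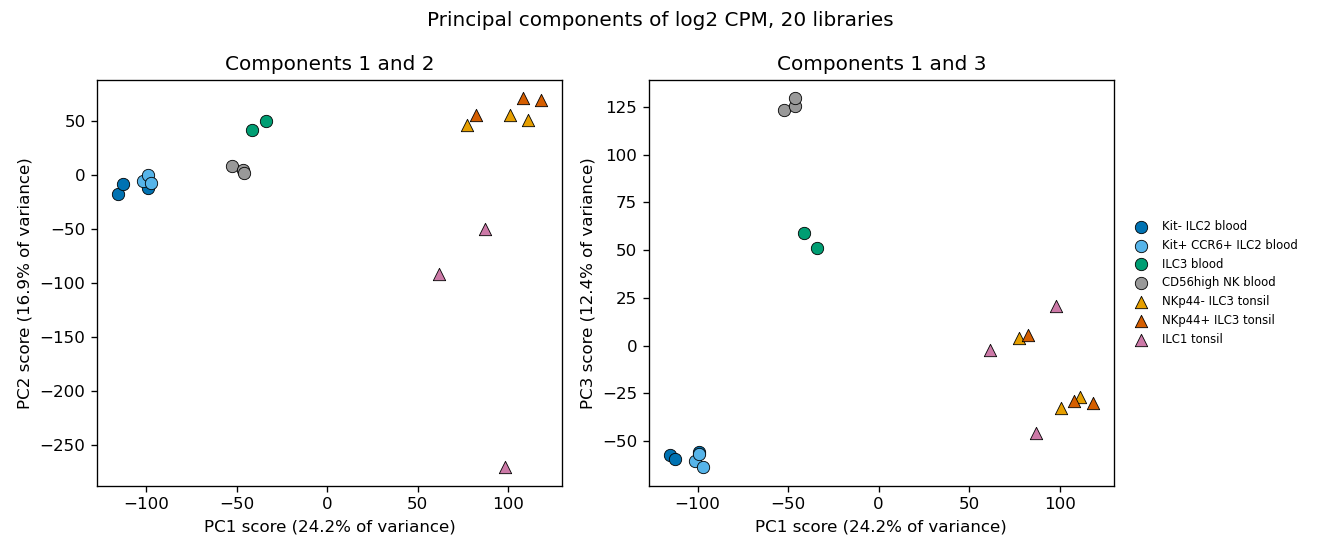
Principal components of log2 CPM over the 20 libraries, each point a library, coloured by group, with circles for blood and triangles for tonsil. Component 1 (24.22% of the variance) parts tonsil from blood, and on component 2 (16.93%) ILC1 replicate 2 stands apart at -270.3.

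The series title names the subsets of ILC2, and the comparison between them asked how blood ILC2 with Kit and CCR6 differed from those without Kit. KIT, the sort marker, stood at 336 ± 57.6 CPM in Kit+ CCR6+ ILC2 and 13.3 ± 1 CPM in Kit- ILC2 (SD, n = 3 each), a log2 fold change of 4.66 ± 0.49 (edgeR adjusted p = 0.000207). Among the other genes with the largest rises was AQP3, a water and glycerol channel (120.1 ± 38.0 against 9.80 ± 5.25 CPM, edgeR adjusted p = 0.00502). ELK3, an ETS family transcription factor, rose as well (60.8 ± 15.4 against 8.26 ± 2.47 CPM, edgeR adjusted p = 0.00164). AFF3, a nuclear factor, stood at 13.9 ± 3.68 against 1.84 ± 0.995 CPM (edgeR adjusted p = 0.00322). IL4I1, a secreted amino acid oxidase on the ILC3 list, stood at 79.7 ± 11.9 against 16.2 ± 0.972 CPM (edgeR adjusted p = 0.00502). The calls of KIT, AQP3, ELK3, AFF3 and IL4I1 held with each library of the comparison left out in turn. Without Kit- replicates 1 and 3 together, a setting chosen after seeing the data that left 1 Kit- library, all 5 lost them (edgeR adjusted p = 0.124, 0.397, 0.337, 0.167 and 0.466). Of the 16 named genes called here, 0 held in every alternative and 5 in every alternative set beforehand. Of 16841 genes tested, 37 were higher and 5 lower in Kit+ CCR6+ ILC2 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05).

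**Figure D2:**
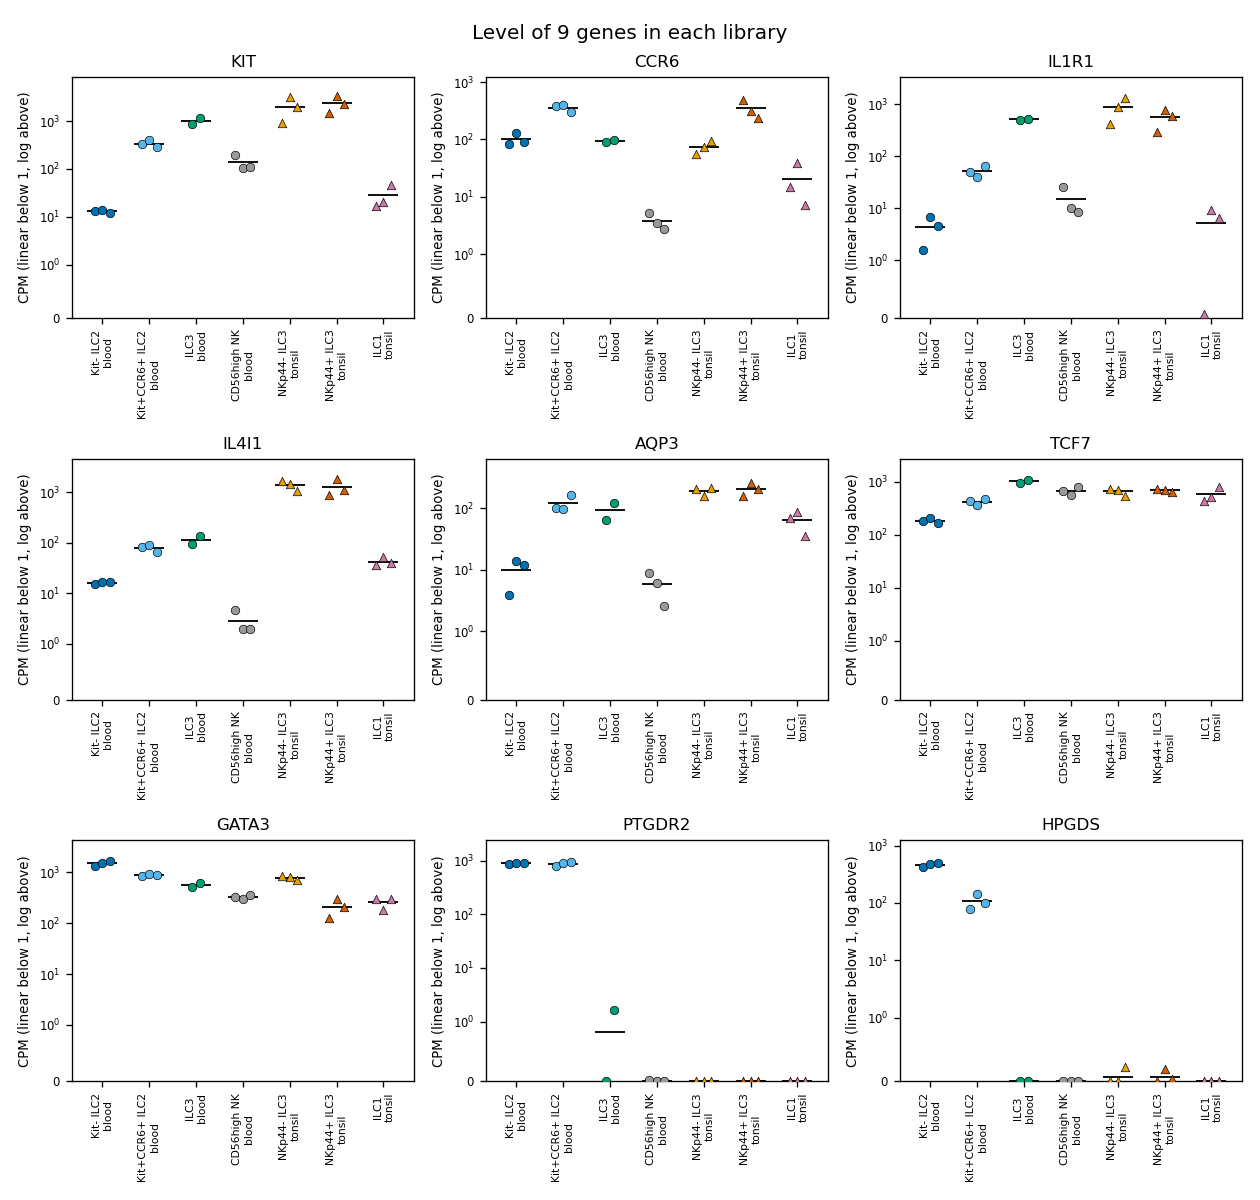
Level of 9 genes in each library on a CPM axis that is linear below 1 and logarithmic above, with each point a library, each line a group mean, circles for blood and triangles for tonsil. KIT, IL4I1 and AQP3 were called higher in Kit+ CCR6+ than Kit- ILC2, while CCR6, IL1R1, GATA3, PTGDR2 and HPGDS were not called between these groups in the fit without the replicate block.

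As a group, the ILC3 markers were higher in Kit+ CCR6+ ILC2. Their list held the sort markers KIT and CCR6, so part of this shift could follow from the gate. Without these 2 genes the list still passed (camera adjusted p = 0.00918 with an estimated correlation), in a check chosen after seeing the data. Of 21 measured members, 2 were called over all genes (KIT and IL4I1) and 8 when adjusted over the list alone, with a median log2 fold change of 1.18 (camera adjusted p = 1.15e-09, and adjusted p = 0.0009 with an estimated correlation). The type 17 genes, which share members with that list, CCR6 included, had a median of 1.26 over 16 members (camera adjusted p = 3.85e-07, and adjusted p = 0.0009 with an estimated correlation). Of these, 1 was called over all genes, the drug efflux pump ABCB1 (43.3 ± 4.21 against 8.81 ± 7.43 CPM), while 8 were higher and 1 lower when adjusted over the list alone. Members that did not pass included the sort marker CCR6, a chemokine receptor (360.6 ± 52.7 against 100.4 ± 24.2 CPM, edgeR adjusted p = 0.145), and IL1R1, the interleukin 1 receptor (52.3 against 4.34 CPM, edgeR adjusted p = 0.165). IL23R, a receptor chain for interleukin 23, had no read in Kit- ILC2 and 3.44 ± 2.5 CPM in Kit+ CCR6+ ILC2. This is at least 87.5-fold higher against a floor of 3 reads over the group, and did not pass either (edgeR adjusted p = 0.28). With the replicate number as a block 4 ILC3 markers were called (KIT, IL4I1, CCR6 and LTB). CCR6 thus passed (edgeR adjusted p = 0.021), while IL1R1 (0.0718) and IL23R (0.216) did not.

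The ILC2 markers were lower as a group in Kit+ CCR6+ ILC2. Over 21 members the median log2 fold change was -0.58 (camera adjusted p = 1.02e-06, and adjusted p = 0.00372 with an estimated correlation). Singly, 0 were called over all genes by edgeR and 0 by DESeq2, 1 was lower when adjusted over the list alone, and at an unadjusted p under 0.05 there were 4 lower and 1 higher. HPGDS, a prostaglandin D2 synthase, stood at 107 ± 33.5 against 460.1 ± 39.3 CPM (edgeR adjusted p = 0.207) and GATA3 at 899.9 ± 56.2 against 1532 ± 181 CPM (edgeR adjusted p = 0.453). With the replicate number as a block GATA3 passed (adjusted p = 0.0123) and HPGDS did not (0.116). PTGDR2, the prostaglandin D2 receptor CRTH2, was at 884 ± 89.8 and 893 ± 20.3 CPM. The mast cell and basophil markers, which also hold HPGDS, had 0 called by edgeR and by DESeq2 over all genes, and 1 lower both when adjusted over the list alone and at an unadjusted p under 0.05. Their median over 6 members was -1.72, or -0.99 with members at 0 reads set to their bound (camera adjusted p = 0.00593, and adjusted p = 0.0496 with an estimated correlation).

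TCF7, a transcription factor of naive and early lymphocytes, rose from 184 ± 20.3 to 426 ± 58.1 CPM, and the cytokine TNF from 1.60 ± 0.492 to 17.1 ± 7.08 CPM. TCF7 was no longer called without Kit- replicate 1 or 3 or Kit+ CCR6+ replicate 1 or 3 (edgeR adjusted p up to 0.0956), TNF not without Kit- replicate 1 (0.0613), and ABCB1 kept its call in 1 of 6 such fits (up to 0.197). Of the 5 lower genes the rule named FAM46A (63.6 ± 7.80 against 159 ± 25.6 CPM) and MAP3K8, a kinase of inflammatory signalling (46.7 ± 1.74 against 91.6 ± 10.6 CPM). Each of these 2 kept its call in 1 of the 6 fits that left out a library, with edgeR adjusted p up to 0.104 and 0.101. The other 3 lay outside the rule or reached the text only as a list member, and were chosen after their values were seen. They were CD2, an adhesion receptor of T and NK cells (9 against 272 reads), MYO1E (1 against 93 reads, a ratio of 125 with a 95% counting interval of 21.9 to 4980), and HLA-DRA, an MHC class II chain. HLA-DRA had no read in Kit+ CCR6+ ILC2 and 5.97, 0 and 56.38 CPM in Kit- replicates 1 to 3, at least 710-fold lower on average, and kept its call in 1 of 6 such fits (up to 0.222).

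Markers of monocytes were present in the Kit- libraries beside these differences. The summed myeloid markers stood at 167.7, 14.8 and 307.9 CPM in Kit- replicates 1, 2 and 3, against 7.49 to 13.79 CPM in the Kit+ CCR6+ libraries. LYZ, the lysozyme gene, stood at 49.92, 0 and 24.43 CPM in the same Kit- libraries. The 16 myeloid markers were lower as a group in Kit+ CCR6+ ILC2 (median -6.38, or -6.08 at the bounds, camera adjusted p = 5.6e-11, and adjusted p = 0.106 with an estimated correlation). Of them edgeR called 0 over all genes and 9 when adjusted over the list alone, with 10 at an unadjusted p under 0.05 and 3 by DESeq2. MHC class II was lower (median -0.97, camera adjusted p = 0.0473, and adjusted p = 0.398 with an estimated correlation), with 1 of 12 called and 2 when adjusted over the list alone. Without Kit- replicates 1 and 3, chosen after seeing the data, the myeloid and MHC class II lists moved upward instead and did not pass (camera adjusted p = 0.327 and 0.472). T cell markers were lower too (median -0.71, camera adjusted p = 0.00305, and adjusted p = 0.151 with an estimated correlation). Of 16 of these, edgeR called 0 over all genes and 3 when adjusted over the list alone, with 5 at an unadjusted p under 0.05 and 1 by DESeq2. Their summed level went the other way, at 1111 ± 105.1 CPM in Kit+ CCR6+ and 987 ± 87.26 CPM in Kit- ILC2 (SD, n = 3 each). B and plasma cell markers were lower (median -4.18, or -1.83 at the bounds, camera adjusted p = 0.0473, and adjusted p = 0.426 with an estimated correlation). Of 17 of these, edgeR called 0 over all genes and 0 when adjusted over the list alone, with 4 at an unadjusted p under 0.05 and 2 by DESeq2.

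Further lists passed only with the preset correlation. Lower were the type 1 and cytotoxic genes (median -1.34 over 33 genes, camera adjusted p = 0.00375, and adjusted p = 0.237 with an estimated correlation). When adjusted over the list alone, 4 of them were lower and 1 higher. Their summed level went the other way, at 1580 ± 120.4 CPM in Kit+ CCR6+ and 1307 ± 13.32 CPM in Kit- ILC2 (SD, n = 3 each). Also lower were the cytosolic ribosomal proteins (median -0.27 over 28 genes, camera adjusted p = 2.24e-13, and adjusted p = 0.116 with an estimated correlation), with 0 when adjusted over the list alone. Naive and circulating lymphocyte genes were higher (median 0.22, camera adjusted p = 0.016, and adjusted p = 0.124 with an estimated correlation), with 1 of 15 called, TCF7, and 2 higher and 1 lower when adjusted over the list alone. So were the immediate early and heat shock genes (median 0.44 over 26 genes, camera adjusted p = 4.29e-05, and adjusted p = 0.22 with an estimated correlation), with 2 when adjusted over the list alone. Cytokine receptors were higher (median 0.20 over 33 genes, camera adjusted p = 0.02, and adjusted p = 0.117 with an estimated correlation), again with 2 when adjusted over the list alone. Glycolysis was higher (median 0.26 over 20 genes, camera adjusted p = 0.000534, and adjusted p = 0.208 with an estimated correlation), with 3 when adjusted over the list alone. In the type 1, ribosomal, immediate early, cytokine receptor and glycolysis lists edgeR called 0 over all genes. At an unadjusted p under 0.05 they had 11, 6, 7, 6 and 4 genes, and DESeq2 called 4, 0, 2, 3 and 2. With the replicate number as a block edgeR called 2, 0, 4, 0 and 3, among them FOS (adjusted p = 0.00187), ZFP36 (0.00173), SLC2A3 (0.012) and PKM (0.00987). The block called 0 of the MHC class II genes, and HLA-DRA was lost (adjusted p = 0.0636). In the naive list it called CCR7 (edgeR adjusted p = 0.0236) besides TCF7, and in the homing list CCR6 and CCR7. In the residency list it called TNFRSF18 (edgeR adjusted p = 0.0305). Among the effector cytokines it called TNF and LTB higher and CCL3 lower. Effector cytokines and chemokines did not pass (camera adjusted p = 0.262), nor did chemokine receptors and homing (0.186), tissue residency and activation (0.212), the cell cycle (0.0805) and plasmacytoid dendritic cell markers (0.0568). The interferon response (0.43), progenitor markers (0.517), erythroid and platelet markers (0.638) and epithelial and stromal markers (0.967) did not pass either, and in these the median and the test differed in sign.

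The count of called genes depended on the libraries and on the fit, and rose with DESeq2, with only the groups compared and with only the blood libraries. With the replicate number as a block it was 110 (96 higher, 14 lower), while it was 14 and 24 without Kit- replicate 1 or 3, 21 and 16 without Kit+ CCR6+ replicate 1 or 3, and 7 without Kit- replicates 1 and 3 together, a setting chosen after seeing the data.

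Kit+ CCR6+ ILC2 were next set against blood ILC3. PTGDR2 stood at 884 ± 89.8 CPM (SD, n = 3) against 0.819 ± 1.16 CPM in ILC3 (SD, n = 2), a log2 fold change of 9.98 ± 1 (edgeR adjusted p = 0.00037). HPGDS and NEFL, the neurofilament light chain, had no read in ILC3 and were at least 2030-fold and at least 2370-fold higher in Kit+ CCR6+ ILC2. RORA, a nuclear receptor needed for ILC2, stood at 204 ± 30.0 against 24.1 ± 3.50 CPM (3.08 ± 0.35, edgeR adjusted p = 7.81e-05). IL10RA, the interleukin 10 receptor chain, stood at 1967 ± 183 against 200.9 ± 90.9 CPM. In the other direction, TGM2, a transglutaminase, ADAM28, a metalloprotease, and NCR1, the activating receptor NKp46, had no read in Kit+ CCR6+ ILC2 and were at least 6070-fold, 1470-fold and 603-fold lower. KLRC1, encoding the lectin receptor NKG2A, stood at 2.39 ± 0.549 against 212 ± 96.1 CPM (edgeR adjusted p = 8.99e-06). TYROBP, a signalling adaptor, stood at 5.32 ± 1.32 against 211 ± 0.44 CPM (edgeR adjusted p = 5.11e-05).

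Of 21 ILC2 markers, 5 were higher over all genes and 14 when adjusted over the list alone (median 3.99, or 3.10 at the bounds, camera adjusted p = 2.8e-17, and adjusted p = 0.000168 with an estimated correlation). Of the ILC3 markers 5 were lower, among them TYROBP and the HMG-box factor TOX2 (1.27 ± 1.28 against 168 ± 78.3 CPM), with 9 lower and 1 higher when adjusted over the list alone (median -2.15, camera adjusted p = 2.91e-05, and adjusted p = 0.00778 with an estimated correlation). KIT itself, at 1016 ± 187 CPM in ILC3, did not pass (edgeR adjusted p = 0.09), nor did CCR6 at 93.9 ± 3.97 CPM in ILC3 (edgeR adjusted p = 0.058). The progenitor markers were lower as a group (camera adjusted p = 0.00022, and adjusted p = 0.0239 with an estimated correlation), with 1 called and 4 when adjusted over the list alone. The 1 called was SPINK2 (0.558 ± 0.602 against 111 ± 4.99 CPM). Type 1 and cytotoxic genes were lower, with 7 of 33 called, and 11 lower and 2 higher when adjusted over the list alone (camera adjusted p = 5.82e-05, and adjusted p = 0.18 with an estimated correlation). Among them was IL2RB, a receptor chain for several interleukins (23.1 ± 4.82 against 367 ± 66.5 CPM). MHC class II was lower, with 4 of 12 called and 6 when adjusted over the list alone (camera adjusted p = 3.94e-06, and adjusted p = 0.139 with an estimated correlation). The called genes included CD74, the invariant chain (338 ± 46.5 against 944 ± 36.3 CPM). T cell markers were higher, with 3 of 16 called, also when adjusted over the list alone (median 1.07, camera adjusted p = 0.00172, and adjusted p = 0.175 with an estimated correlation). In all, 168 genes were higher and 240 lower (edgeR adjusted p under 0.05). The genes named singly in these 2 paragraphs as higher or lower kept their calls with each library left out in turn. The count fell to 176 and 168 without ILC3 replicate 1 or 2, and to 237, 251 and 238 without Kit+ CCR6+ replicate 1, 2 or 3. It rose with DESeq2, with the replicate number as a block, with only the groups compared and with only the blood libraries.

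Kit- ILC2 were set against blood ILC3 as well. KIT stood at 13.3 ± 1 CPM (SD, n = 3) against 1016 ± 187 CPM (SD, n = 2), a log2 fold change of -6.26 ± 0.54 (edgeR adjusted p = 3.15e-06). IL1R1 stood at 4.34 ± 2.66 against 521 ± 14.0 CPM (-6.90 ± 1.04, edgeR adjusted p = 0.000687). IL23R had no read in Kit- ILC2 and 29.9 ± 8.96 CPM in ILC3, at least 761-fold lower. TCF7 stood at 184 ± 20.3 against 1040 ± 89.5 CPM (-2.5 ± 0.23, edgeR adjusted p = 5.33e-06). TNFRSF18, the costimulatory receptor GITR, stood at 87.4 ± 16.6 against 637 ± 17.9 CPM (edgeR adjusted p = 0.000283). HPGDS, with no read in ILC3, was at least 8730-fold higher in Kit- ILC2, and PTGDR2 stood at 893 ± 20.3 against 0.819 ± 1.16 CPM (10 ± 1, edgeR adjusted p = 0.000212).

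Of the ILC3 markers 10 of 21 were lower, also when adjusted over the list alone (median -4.02, or -3.55 at the bounds, camera adjusted p = 4.81e-12, and adjusted p = 0.000115 with an estimated correlation). Of the ILC2 markers 8 of 21 were higher and 14 when adjusted over the list alone (median 4.79, camera adjusted p = 9.24e-22, and adjusted p = 4.68e-05 with an estimated correlation). CCR6 did not differ by more than the spread, at 100.4 ± 24.2 against 93.9 ± 3.97 CPM (edgeR adjusted p = 0.993). Another lower group was the type 17 genes (4 of 16, 5 when adjusted over the list alone, camera adjusted p = 0.00103, and adjusted p = 0.016 with an estimated correlation). The naive and circulating lymphocyte genes were lower too (3 of 15, 5 when adjusted over the list alone, camera adjusted p = 0.00125, and adjusted p = 0.0419 with an estimated correlation). The T cell markers were higher, with 2 of 16 called and 6 when adjusted over the list alone (camera adjusted p = 2.31e-07, and adjusted p = 0.0222 with an estimated correlation). The cytosolic ribosomal proteins were higher, with 10 of 28 called and 21 when adjusted over the list alone (median 0.60, camera adjusted p = 3.9e-18, and adjusted p = 0.0664 with an estimated correlation). Progenitor markers were lower, with 2 of 8 called, also when adjusted over the list alone (median -3.94, or -3.08 at the bounds, camera adjusted p = 0.000497, and adjusted p = 0.0222 with an estimated correlation). The myeloid markers were higher in Kit- ILC2 (median 5.58, or 4.22 at the bounds, camera adjusted p = 0.00118, and adjusted p = 0.391 with an estimated correlation). Of 16 of them edgeR called 0 over all genes and 0 when adjusted over the list alone, with 6 at an unadjusted p under 0.05 and 3 by DESeq2. Their sum was 167.7, 14.8 and 307.9 CPM in Kit- replicates 1 to 3, against 21.68 and 87.47 CPM in the ILC3 libraries, so Kit- replicate 2 lay below both. In all, 248 genes were higher and 440 lower in Kit- ILC2 (edgeR adjusted p under 0.05). DESeq2, the replicate block, a fit of only the groups compared and a fit of only the blood libraries each called more genes. Leaving out ILC3 replicate 1 or 2 gave 283 and 248 genes, leaving out Kit- replicate 1, 2 or 3 gave 374, 418 and 432, and leaving out Kit- replicates 1 and 3, chosen after seeing the data, gave 132.

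Kit- ILC2 and CD56high NK cells, another innate lymphocyte of blood, differed in 1384 genes, 675 higher and 709 lower in Kit- ILC2 (edgeR adjusted p under 0.05). More genes were called with DESeq2, with only the groups compared and with only the blood libraries. HPGDS had no read in NK cells and was at least 16900-fold higher, and HLF, a bZIP transcription factor, was at least 2410-fold higher (65.7 ± 6.34 CPM, SD, n = 3). PTGDR2 had 1 read over the NK libraries, a ratio of 98600 with a 95% counting interval of 17700 to 3890000. GATA3 stood at 1532 ± 181 against 329 ± 22.9 CPM (2.22 ± 0.25, edgeR adjusted p = 1.92e-05). HPGD, which degrades prostaglandins, stood at 297 ± 37.6 against 3.24 ± 1.31 CPM. IL2RB stood at 18.1 ± 7.57 against 5389 ± 1210 CPM (-8.22 ± 0.60, edgeR adjusted p = 2.04e-07). IL12RB2, an interleukin 12 receptor chain, stood at 0.401 ± 0.334 against 319 ± 46.9 CPM, and CCR7, the lymph node homing receptor, at 7.25 ± 7.39 against 415 ± 6.42 CPM. NCAM1, which encodes CD56, stood at 0.231 ± 0.165 against 204 ± 15.4 CPM (edgeR adjusted p = 0.00372).

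Of the ILC2 markers 18 of 21 were higher, also when adjusted over the list alone (median 6.52, or 6.5 at the bounds, camera adjusted p = 7.38e-25, and adjusted p = 7.04e-06 with an estimated correlation). Of the 33 type 1 and cytotoxic genes 25 were lower and 1 higher, and 27 lower when adjusted over the list alone (median -6.11, camera adjusted p = 2.02e-29, and adjusted p = 0.000475 with an estimated correlation). T cell markers moved both ways, with 7 higher and 2 lower, and 10 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.000189, and adjusted p = 0.0973 with an estimated correlation). The costimulatory receptor CD28 was among the higher ones, at 90.3 ± 5.03 against 0.287 ± 0.497 CPM (edgeR adjusted p = 1.79e-05). The ILC3 markers had 4 higher and 5 lower, or 6 and 5 when adjusted over the list alone, and did not pass as a group (camera adjusted p = 0.847). CCR6 was higher in Kit- ILC2 (100.4 ± 24.2 against 3.86 ± 1.26 CPM) and KIT lower (13.3 ± 1 against 138 ± 51.5 CPM). The myeloid markers were higher in Kit- ILC2, with 2 of 16 called and 9 when adjusted over the list alone (camera adjusted p = 7.86e-05, and adjusted p = 0.341 with an estimated correlation). Their sum was 15.8 to 38.78 CPM in the NK libraries and, as above, 14.8 to 307.9 CPM in Kit- ILC2. Without Kit- replicates 1 and 3, chosen after seeing the data, the count of called genes was 442, and without NK replicate 3 it was 878.

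In tonsil, NKp44+ ILC3 were compared with NKp44- ILC3. NCR2, the sort marker, stood at 146 ± 144 against 0.812 ± 0.840 CPM (SD, n = 3 each, edgeR adjusted p = 0.0385). It kept that call in 1 of the 6 fits that left out a library, with adjusted p up to 0.201 without NKp44+ replicate 1. CPNE7, a calcium-dependent membrane binding protein, stood at 332 ± 227 against 7.77 ± 1.91 CPM (5.41 ± 0.64, edgeR adjusted p = 0.000294). CCR6 stood at 347 ± 132 against 74.5 ± 18.5 CPM (2.22 ± 0.45, edgeR adjusted p = 0.0193). Lower in NKp44+ ILC3 was S1PR1, the receptor used for tissue egress, at 25.0 ± 6.29 against 176 ± 53.8 CPM (-2.82 ± 0.29, edgeR adjusted p = 7.66e-05). IL10RA (16.1 ± 10.1 against 200.4 ± 25.3 CPM, edgeR adjusted p = 4.42e-05), GATA3 (209.9 ± 84.7 against 789 ± 58.2 CPM, edgeR adjusted p = 0.000685) and PRF1, which encodes perforin (1.13 ± 1.28 against 49.3 ± 14.2 CPM, edgeR adjusted p = 0.000688), were lower too.

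As groups, the naive and circulating lymphocyte genes were lower (3 of 15, 6 when adjusted over the list alone, median -1.06, camera adjusted p = 7.09e-07, and adjusted p = 0.0102 with an estimated correlation). The chemokine receptors and homing genes were lower with members both ways (2 higher and 4 lower of 30, and 8 lower when adjusted over the list alone, camera adjusted p = 0.000335, and adjusted p = 0.0172 with an estimated correlation). The ILC3 markers were higher (2 of 21, 4 when adjusted over the list alone, median 0.22, camera adjusted p = 0.000248, and adjusted p = 0.0172 with an estimated correlation). So were the type 17 genes (1 of 16, with 3 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.00576, and adjusted p = 0.027 with an estimated correlation). The immediate early and heat shock genes were lower, with 2 of 26 called and 11 when adjusted over the list alone (camera adjusted p = 5.04e-11, and adjusted p = 0.0733 with an estimated correlation). KIT did not differ beyond the spread (2345 ± 936 against 2006 ± 1107 CPM, edgeR adjusted p = 0.952). In all, 62 genes were higher and 144 lower (edgeR adjusted p under 0.05). A fit of these 6 libraries alone called 0 genes with edgeR (1455 at an unadjusted p under 0.05, and 675 by DESeq2 on all libraries), and a fit of the 9 tonsil libraries, chosen after seeing the data, called 8 (972 at an unadjusted p under 0.05). The count was 118 and 124 without NKp44- replicate 2 or 3 and 120 and 79 without NKp44+ replicate 1 or 3. It was higher with the replicate number as a block. CCR6 lost its call in 3 of the 6 fits that left out a library, with NKp44- replicate 1, NKp44- replicate 2 or NKp44+ replicate 1 left out (edgeR adjusted p up to 0.0882).

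NKp44+ ILC3 against ILC1 of tonsil gave 1132 genes higher and 961 lower (edgeR adjusted p under 0.05). KIT stood at 2345 ± 936 against 28.1 ± 16.3 CPM (SD, n = 3 each, log2 fold change 6.38 ± 0.53, edgeR adjusted p = 1.74e-06). IL4I1 stood at 1278 ± 509 against 42.1 ± 8.18 CPM (4.92 ± 0.37, edgeR adjusted p = 6.42e-07) and CCR6 at 347 ± 132 against 20.2 ± 16.2 CPM. TNFSF11, the cytokine RANKL, stood at 200.1 ± 37.1 against 0.519 ± 0.899 CPM, and the chemokine CCL20 at 107 ± 20.7 against 1.65 ± 0.625 CPM. TNFSF4, the OX40 ligand, was at least 3700-fold higher, with no read in ILC1. Cytotoxic genes were lower in NKp44+ ILC3. PRF1 stood at 1.13 ± 1.28 against 255 ± 16.9 CPM (-7.94 ± 0.80, edgeR adjusted p = 1.2e-05), and GZMK, a granule protease, was at least 4710-fold lower with no read in NKp44+ ILC3. TBX21, the type 1 transcription factor T-bet, stood at 3.43 ± 2.02 against 112 ± 60.7 CPM (edgeR adjusted p = 8.34e-05) and IL10RA at 16.1 ± 10.1 against 617 ± 63.0 CPM (-5.27 ± 0.37, edgeR adjusted p = 3.9e-07).

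Of the ILC3 markers 15 of 21 were higher and none lower, and 18 when adjusted over the list alone (median 4.95, camera adjusted p = 6.26e-13, and adjusted p = 0.000195 with an estimated correlation). The type 17 genes had 8 higher, and 10 when adjusted over the list alone (median 2.60, camera adjusted p = 7.53e-06, and adjusted p = 0.00247 with an estimated correlation). The type 1 and cytotoxic genes had 21 lower and 2 higher, and 3 higher when adjusted over the list alone (median -5.03, camera adjusted p = 1.21e-12, and adjusted p = 0.0133 with an estimated correlation). The naive and circulating lymphocyte genes were lower (6 of 15, also when adjusted over the list alone, camera adjusted p = 6.12e-06, and adjusted p = 0.00666 with an estimated correlation). LEF1, a relative of TCF7, stood at 4.64 ± 4.27 against 405 ± 165 CPM. Homing genes were lower with members both ways (3 higher and 10 lower of 30, or 4 and 12 when adjusted over the list alone, camera adjusted p = 0.000379, and adjusted p = 0.0132 with an estimated correlation). Cytosolic ribosomal proteins were lower, with 18 of 28 called and 21 when adjusted over the list alone (camera adjusted p = 1.17e-16, and adjusted p = 0.0786 with an estimated correlation).

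Markers of T and B lineage cells were higher in the ILC1 libraries. Of 16 T cell markers 9 were lower in NKp44+ ILC3, also when adjusted over the list alone (median -4.35, camera adjusted p = 2.24e-09, and adjusted p = 0.00861 with an estimated correlation). CD3D, a chain of the T cell receptor complex, stood at 1.23 ± 0.293 against 95.5 ± 42.3 CPM. The summed T cell markers were 1634 to 2094 CPM in ILC1 and 224.1 to 1096 CPM in the tonsil ILC3 libraries. Of 17 B and plasma cell markers 7 were lower, and 9 when adjusted over the list alone (median -5.15, or -4.87 at the bounds, camera adjusted p = 1.89e-05, and adjusted p = 0.159 with an estimated correlation). MZB1, a plasma cell chaperone, had 3 reads in NKp44+ ILC3 against 517 ± 438 CPM in ILC1, a ratio of 14200 with a 95% counting interval of 4860 to 68900. The summed B and plasma cell markers were 2430, 7184 and 288.8 CPM in ILC1 replicates 1, 2 and 3. Without ILC1 replicates 1 and 2, a setting chosen after seeing the data, 1420 genes were called, of which 854 were among the 2093. Without NKp44+ replicate 2 or 3 the count was 1391 and 1216, and a fit of the tonsil libraries alone, also chosen after seeing the data, called 587.

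**Figure D3:**
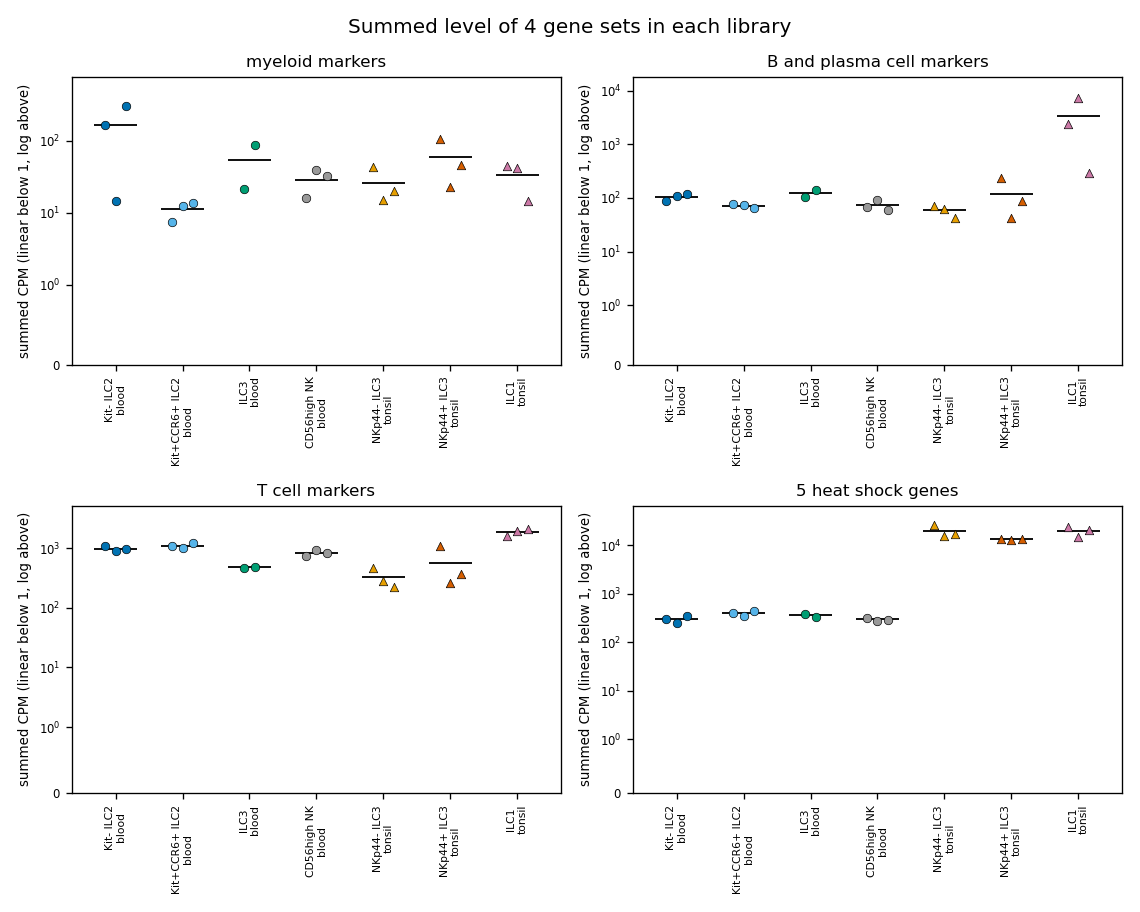
Summed CPM per library of the myeloid markers, the B and plasma cell markers, the T cell markers and 5 heat shock genes, each point a library, with circles for blood and triangles for tonsil. ILC1 replicates 1 and 2 stand at 2430 and 7184 CPM for the B and plasma cell markers, and Kit- ILC2 replicates 1 and 3 at 167.7 and 307.9 CPM for the myeloid markers.

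The 100 genes that best marked NKp44+ ILC3 against ILC1 in the tonsil libraries were then tested in the blood ILC2 comparison. It set other libraries against each other, but its spread came from the fit of all 20 libraries, tonsil included. The set also held KIT, a sort marker. Of the 100 genes, 59 had a positive and 36 a negative log2 fold change in Kit+ CCR6+ against Kit- ILC2, with a median of 0.16 (camera adjusted p = 0.0004, and adjusted p = 0.028 with an estimated correlation). The 6 called higher were IL4I1, KIT, AFF3, NRIP1, TLE1 and MCAM, and the 1 called lower was MAP3K8. The 100 genes that best marked ILC1 had 52 positive and 48 negative values (camera adjusted p = 0.275, and adjusted p = 0.451 with an estimated correlation), with FAM46C and PDE4B called higher and none lower. With 50 genes per direction the ILC1 genes passed too (camera adjusted p = 0.0338), so the contrast between the 2 sets depended on their size. The ILC1 genes came from libraries of which 2 of 3 held B lineage transcripts, and FAM46C is also a plasma cell gene.

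Blood ILC3 and NKp44- ILC3 of tonsil differed in 2202 genes, 954 higher and 1248 lower in blood (edgeR adjusted p under 0.05). Heat shock genes were lower in blood. HSPA1A, an inducible chaperone whose split of reads with the near-identical HSPA1B is uncertain, stood at 14.2 ± 1.05 CPM (SD, n = 2) against 3940 ± 1028 CPM (SD, n = 3), a log2 fold change of -8.11 ± 0.45 (edgeR adjusted p = 3.01e-08). The cochaperones followed, with HSPH1 at 105.8 ± 13.2 against 3935 ± 1378 CPM and DNAJB1 at 229 ± 19.1 against 7551 ± 3706 CPM. VEGFA, a growth factor for vessels, and DUSP8, a phosphatase of MAP kinases, had no read in blood ILC3 and were at least 1670-fold and 739-fold lower. IL4I1 stood at 114 ± 26.1 against 1406 ± 329 CPM (-3.62 ± 0.41, edgeR adjusted p = 3.3e-05). IL21R, the interleukin 21 receptor, stood at 9.54 ± 2.25 against 136 ± 29.5 CPM. Higher in blood was TXNIP, an inhibitor of thioredoxin (9177 ± 389 against 756 ± 212 CPM, edgeR adjusted p = 0.00169). So was PRF1 (465 ± 136 against 49.3 ± 14.2 CPM, edgeR adjusted p = 0.00338). KLRG1, an inhibitory lectin receptor, was higher as well (108 ± 39.7 against 11.5 ± 3.47 CPM, edgeR adjusted p = 0.000274).

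As a group the immediate early and heat shock genes were lower in blood ILC3 (16 of 26, and 18 lower with 4 higher when adjusted over the list alone, median -1.72, camera adjusted p = 2.42e-08, and adjusted p = 0.172 with an estimated correlation). Tissue residency and activation genes were lower (6 of 20, 7 when adjusted over the list alone, median -1.80, or -1.42 at the bounds, camera adjusted p = 0.00438, and adjusted p = 0.127 with an estimated correlation). DUSP6 stood at 94.5 ± 24.2 against 551 ± 212 CPM and RGS2 at 51.4 ± 3.03 against 245 ± 57.1 CPM. Glycolysis genes were lower with 7 lower and 1 higher of 20, or 8 and 1 when adjusted over the list alone (median -1, camera adjusted p = 0.0143, and adjusted p = 0.416 with an estimated correlation). Among them PFKFB3, which drives glycolytic flux, stood at 46.7 ± 2.53 against 309 ± 118.5 CPM. The ILC3 markers did not pass as a group (1 higher and 2 lower, or 1 and 4 when adjusted over the list alone, camera adjusted p = 0.564). KIT and CCR6 were not called (edgeR adjusted p = 0.199 and 0.712). Tissue and gate differed together here. In 5 heat shock genes (HSPA1A, HSPA1B, HSPA6, DNAJB1 and HSPH1) every tonsil library stood above every blood library, and for the other genes the parts of tissue and gate were not tested. Without ILC3 replicate 1 or 2 the count was 720 and 970, and without NKp44- replicate 2 it was 1381.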

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

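All tests weighed in this part were chosen after the results were seen.

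Of the reads in no annotated gene, ILC1 replicate 2 held the highest share, 32.4%, where the lowest library had 21.2% and the median was 23.8%. Ambiguous reads reached 2.19% in Kit- ILC2 replicate 1, against a lowest share of 1.04% and a median of 1.97%. Reads that did not align reached 5.16% in ILC1 replicate 2, against a lowest share of 1.6% and a median of 2.36%. Reads aligned to several places reached 25.7% in ILC1 replicate 2, against a lowest share of 5.75% and a median of 6.3%, and the range by group was 5.75% to 6.33% over all blood libraries, 8.31% to 9.86% in NKp44- ILC3, 7.46% to 8.68% in NKp44+ ILC3 and 8.87% to 25.7% in ILC1. These 4 classes of reads are listed because they were outside the comparisons and above what a count of 0 allows, which does not show that they are unusual.

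The first pattern is the B and plasma cell markers of the ILC1 libraries, which summed to 2430, 7184 and 288.8 CPM in replicates 1, 2 and 3. B lineage cells or their RNA in replicates 1 and 2 are a candidate source, though the gate for ILC1 should remove such cells. Of 12 further plasma cell genes, 0 of them in that marker list and 9 also at 1 CPM or more in every tonsil ILC3 library, 12 were higher in both libraries than in all 6 tonsil ILC3 libraries, against a median of 1 and a 95th percentile of 3 in 10000 random lists matched on expression. Among them were IGLL5 at 1273.7, 4017.34 and 3.65 CPM and DERL3 at 307.51, 615.62 and 5.6 CPM in replicates 1, 2 and 3, and since the libraries were picked for the same kind of transcript, the test shows only that the pattern reached genes outside the marker list. Expression by ILC1 of every library stays open on 1 library: the marker sum differed 24.9-fold between the highest and lowest ILC1 library, and replicate 3 lay at or below the highest tonsil ILC3 library in 10 of the 12 genes but above it in the marker sum (288.8 against 230.9 CPM).

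The second pattern is the level of heat shock genes in NKp44- ILC3 of tonsil. The NKp44- gate as its only cause is argued against, since the lowest NKp44+ ILC3 or ILC1 tonsil library stood at least 15.4-fold above the highest blood library in each of 5 heat shock genes. A partial effect of the gate stays open. As given above, the immediate early and heat shock list was lower in NKp44+ than NKp44- ILC3 (camera adjusted p = 5.04e-11, and adjusted p = 0.0733 with an estimated correlation). Handling of the tonsil tissue before the sort and a difference between the tissues cannot be told apart, because no tonsil sample was handled in another way. The lowest tonsil library stood 29.1-fold above the highest blood library in the summed level of the 5 genes, and HSPA1A alone ranged from 2523 CPM upward in tonsil and up to 22.97 CPM in blood.

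The third pattern is the shift of ILC3 markers up and ILC2 markers down in Kit+ CCR6+ against Kit- ILC2. Transcripts of other cell types in Kit- replicates 1 and 3 as the whole cause stay open, since without these libraries only Kit- replicate 2 was left. The lists then moved the same way (camera adjusted p = 4.84e-06 for ILC3 and 3.14e-06 for ILC2 markers). These p-values used the preset correlation and a spread assumed from other groups, so they cannot decide. In Kit- replicate 2 the ILC3 markers, KIT and CCR6 included, summed to 1018 CPM, against 2629 to 2960 CPM in Kit+ CCR6+ ILC2. The ILC2 markers summed to 4556 against 3019 to 3322 CPM. The sort markers alone are argued against for the ILC3 markers, where without KIT and CCR6 the camera adjusted p was 0.00918 with an estimated correlation. For the ILC2 markers that check could not decide. Their list held only PTGDR2 of the sort markers, which did not differ (log2 fold change -0.03 ± 0.45 with the replicate block). Leaving it out (camera adjusted p = 0.00507 with an estimated correlation) could not remove the shift. A biological difference between the sorted subsets, and other effects of the gate, stay open as hypotheses and were not tested further.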

How the results depend on the processing

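Fits of a single tissue, fits without ILC1 libraries and fits without libraries that held transcripts of other cell types were chosen after seeing the data. In each case below the cause was not tested. Counts of called genes in the order of the report were 42, 408, 688, 1384, 206, 2093 and 2202. With DESeq2 they were 227, 1117, 1485, 2284, 675, 3236 and 3495. With only the groups compared the ILC2 comparison gave 245, Kit+ CCR6+ ILC2 and ILC3 1492, Kit- ILC2 and ILC3 2011, Kit- ILC2 and NK cells 3397, the tonsil ILC3 subsets 0 by edgeR (1455 at an unadjusted p under 0.05, 675 by DESeq2 on all libraries) and NKp44+ ILC3 and ILC1 250. With only libraries of the same tissue these 6 were 274, 1747, 2418, 3552, 8 and 587. Without the ILC1 libraries the counts were 87, 830, 1285, 2248, 483 and, for blood against tonsil ILC3, 3736. Without Kit- ILC2 replicates 1 and 3 they were 7, 132 and 442 for the comparisons with Kit- ILC2, and 3, 126 and 432 of these genes were shared with the original calls. RLE scaling and no filter on low counts kept every count within 1.5 times and every share of higher calls within 10 percentage points.

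With the replicate block the count was 110 in the ILC2 comparison, 741 and 1135 for Kit+ CCR6+ and Kit- ILC2 against blood ILC3 and 454 for the tonsil ILC3 subsets, and it changed no other count by over 1.5 times. It ended the list calls of glycolysis in Kit+ CCR6+ ILC2 against ILC3 (camera adjusted p = 0.116) and of the interferon response in Kit- ILC2 against ILC3 (0.745), and no list call of the ILC2 comparison. Outside that comparison the block was given only here, though some pairs also correlated over 0.1. Same-numbered NKp44- and NKp44+ ILC3 libraries correlated at 0.192 and 0.188, and Kit+ CCR6+ ILC2 and blood ILC3 at 0.109 and 0.101. NKp44- replicate 1 and NKp44+ replicate 1 had no partner of the same number. In blood 8 of 15 same-numbered pairs had a correlation over 0.1 (0.064 to 0.146) and 15 correlated best with their own number, and in tonsil 3 of 6 (0.07 to 0.192) and 5. Blood ILC3 had 2 libraries, whose deviations from their mean are exact opposites. For the ILC2 groups with ILC3 a best match thus shows only a positive sign. Deviations cancel within a group, so the pairs are not independent. For ILC3 of blood against tonsil no paired analysis was possible, because the number was defined within a tissue.

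With each library left out in turn the counts ranged from 14 to 34, 168 to 251, 248 to 432, 878 to 996, 79 to 227, 1216 to 3097 and 720 to 2628, in the order above. The call of the tonsil NKp44+ genes in blood ILC2 held throughout (camera adjusted p = 6.6e-05 to 0.0109). That of the tonsil ILC1 genes ranged from 0.203 to 0.708, and passed only with 50 genes per direction (0.0338). Without Kit- replicates 1 and 3, MHC class II and the myeloid markers turned upward in the ILC2 comparison without passing (camera adjusted p = 0.472 and 0.327), and LYZ against NK cells had a log2 fold change of 0. That of PTGDR2 in blood against NKp44- ILC3 of tonsil was 0 without ILC3 replicate 2 and 8.655 without ILC3 replicate 1. Of the tests of named genes that were called, DESeq2 kept 347 and lost 1, RLE kept 348 and lost 1, no filter kept 347 and lost 2, the block kept 270 and lost 17, and the fits of only 2 groups kept 273 and lost 70. Leaving out libraries kept 1474, lost 455 and brought 1 to a log2 fold change of 0. In the tonsil ILC3 comparison 0 of the 32 called named genes held in every alternative set beforehand. At 4-fold the simulated ILC2 comparison, with the same spread per gene in every library, called 65.7% of changed genes.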

Other observations

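The tests of gene lists by other splits and of ILC3 genes below were planned before their results were seen, and the tests by other splits of the gene counts were chosen after.

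Against blood ILC3, the genes higher in Kit+ CCR6+ than Kit- ILC2 fell on both sides. Of the 37 genes, 5 were called higher in Kit+ CCR6+ ILC2 than in ILC3, 9 were called lower and 23 were not called, where over all 16841 genes 168 were higher and 240 lower. The 37 were chosen for high values in the same Kit+ CCR6+ libraries, so the split is a description and not a test. CDKN1A, the cell cycle inhibitor p21, stood at 314 ± 97.7 CPM in Kit+ CCR6+ ILC2 (SD, n = 3), 47.5 ± 15.4 CPM in Kit- ILC2 (SD, n = 3) and 28.3 ± 8.16 CPM in ILC3 (SD, n = 2), above both by edgeR (adjusted p = 4.75e-05 and 5.89e-06). LMNA, the nuclear lamina protein lamin A, stood at 678 ± 242, 153 ± 5.68 and 99.1 ± 35.7 CPM (edgeR adjusted p = 0.0108 and 0.000976), and TGFBR3, a coreceptor for TGF-beta, at 148 ± 28.4, 34.0 ± 13.7 and 26.1 ± 5.84 CPM (edgeR adjusted p = 0.0194 and 0.00474). In contrast CXXC5, a zinc finger regulator, stood between the groups at 125 ± 9.07 CPM, with 22.3 ± 1.53 in Kit- ILC2 and 248 ± 50 in ILC3 (edgeR adjusted p = 8.02e-06 and 0.0116), as did the kinase PRKCH at 155 ± 18.4, 54.2 ± 11.6 and 500 ± 71.0 CPM (edgeR adjusted p = 0.0145 and 0.00223). These 5 genes lay outside the naming rule and were chosen after their values were seen.

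The hypothesis that genes higher in Kit+ CCR6+ ILC2 are genes of blood ILC3 was tested against CD56high NK cells, libraries outside that comparison. Of the 37 genes, 24 had a positive log2 fold change in ILC3 against NK cells, with a median of 20 and a 95th percentile of 25 in 10000 random lists matched on expression, and 1368 of the lists had as many. The test leaves the hypothesis open. By edgeR 11 of the genes were called higher in ILC3 than in NK cells and 4 lower.

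Libraries were also regrouped, and 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. In each case below 1 split, the labelled one, gave a result as large. Every other split mixed the compared groups, which moved their difference into the spread, so low counts there were partly set in advance. The ILC2 comparison called 42 genes and the highest other split 1, also among the 4 splits that part all 3 numbered pairs. Kit- ILC2 against NK cells called 1384 genes and the highest other split 0. NKp44+ against NKp44- ILC3 called 206 and the highest other split 71, and NKp44+ ILC3 against ILC1 called 2093 and the highest other split 514. The split with 514 genes set ILC1 replicates 1 and 2, which held B lineage transcripts, together with NKp44+ replicate 1. For lists in the ILC2 comparison the camera p was 1.5e-10 for the ILC3 markers and 0.000536 in the strongest other split, 2.21e-07 and 0.00342 for the ILC2 markers, and 0.0002 and 0.00304 for the tonsil NKp44+ genes.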
